A study of Homo sapiens with 12 samples.

How the data were processed

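RNA captured with anti-flag agarose from A549 cells was sequenced in 12 samples, which fell into 4 groups of 3 by their titles. Per the submitters' processing notes, HISAT2, SAMtools, StringTie and deepTools were used with the GRCh37 genome build. Their versions, roles and order are not given in the sources used here. Per the labels' protocols, equal amounts of RNA were mixed with a commercial spike-in before library preparation. Among the gene rows, 0 carried an ERCC spike-in name, which does not show whether spike-in reads were present.

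The authors deposited a single gene table for the series, with 63568 gene rows, each named by an Ensembl identifier and a symbol, and 12 columns of values. The columns are headed by codes that the sources used here do not explain. A search of all label fields of the 12 samples found 0 of these codes, and no other source used here pairs them with samples. Only the labels and the series text were searched, so a pairing held in other records is not excluded. A column was to be assigned to a sample only where its name matched that sample's labels. Assignment by column order was not made, since nothing in the labels ties the order of columns to the order of samples. Assignment by the values was not made either. The level of HNRNPM was planned as a check of the labels, which it could not be if it set them. TGFβ-responsive genes belong to the outcome under test. The values were inspected when the table was opened, to learn their unit and to see whether column order could be a guide. No assignment was drawn from the values. All 12 columns of per-sample values were therefore left out of every result, and depth per sample is not given.

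The tests, the gene lists and the rule for named genes were fixed before the data were examined. They were not run. The only alternatives computed were looser rules for matching the column codes to the labels.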

Results

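The series was an RNA immunoprecipitation experiment in A549, an established human lung carcinoma cell line. Cells carried either a plasmid for flag-tagged hnRNP M, a nuclear RNA-binding protein that takes part in pre-mRNA splicing, or the empty flag plasmid. Proteins carrying the tag were captured from lysates on anti-flag agarose, and the RNA that came with them was made into sequencing libraries. The empty plasmid gives the background of RNA that binds to the agarose without the bait.

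The labels placed 12 samples in 4 groups of 3 replicates each. The groups were empty flag without TGFβ, empty flag with TGFβ, flag-hnRNP M without TGFβ and flag-hnRNP M with TGFβ. Without TGFβ stands here for the word CTRL in the titles. The labels numbered the replicates 1 to 3 within each group and did not say whether they came from separate cultures. TGFβ is a cytokine that drives epithelial cells towards a mesenchymal state.

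The design implied 5 comparisons. The first pair asked which RNAs were recovered with flag-hnRNP M above the empty-flag background, in cells without and with TGFβ. The next pair asked what TGFβ altered within the flag-hnRNP M pulldown and within the empty-flag pulldown. The fifth asked whether TGFβ altered the enrichment over background, which is the interaction of plasmid and treatment.

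None of the 5 comparisons is reported here. The deposited gene table had 12 columns of values headed by unexplained codes, and 0 of these codes occurred in the labels of the samples. No column was therefore assigned to a sample or to a group, and no level, fold change or count of enriched genes is given for any gene, HNRNPM included.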

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

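The search that found 0 of the 12 column codes in the labels of the samples was repeated with looser rules, chosen after seeing the data. Ignoring case and punctuation, looking for the number of the code alone, and searching the series text in place of the sample labels each found 0 codes as well. No paired analysis was possible because the columns of the deposited table carry no replicate number and could not be assigned to samples. The other settings fixed before the data were examined (normalization, low-count filter, test, samples in the fit, pairing and left-out replicates) were not run, because no column had a group.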
